A study of Homo sapiens with 6 samples.

How the data were processed

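RNA from 12Z cells, an immortalised human endometriotic line, was sequenced after 12 h with myrrh extract at 100 µg/mL or with DMSO, in 3 libraries per group. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made from 1.5 µg of total RNA with an Illumina TruSeq RNA kit. The protocols do not say whether poly(A) RNA was selected, whether the kit marked the strand, or how replicates were set up. Groups were taken from the sample titles, and the replicate numbers only name the libraries.

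The deposited tables hold 1 row per gene, with an Ensembl identifier and a symbol, and 1 column per library. The authors' first table gives estimated counts per gene, as RSEM makes them, that are not scaled between libraries. STAR and RSEM 1.3.1 and the build GRCh38 are named in the submitters' processing notes, while trimming, the annotation release and the strand setting are not given in the sources used here. Between 11.1% and 12.2% of the estimated counts per library, and 29.7% to 30.3% of those above 0, were not whole numbers, since RSEM splits reads that match several genes. Genes with near-identical copies, such as HSPA1A and HSPA1B or HSPA6 and HSPA7, therefore hold shares of reads that are uncertain. The second deposited table holds log2(TPM + 1), made by the authors from TPM, transcript abundance scaled to a fixed sum within each library; undoing the log gave sums of 999429 to 999560 per library. Both tables list 60419 genes, of which 18397 have no symbol. Depth was 22454783 to 27588151 estimated counts per library, and the totals per group did not differ beyond the spread (two-sided exact permutation test, p = 0.3, where 0.1 is the smallest possible).

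Estimated counts were rounded to whole numbers, genes with low counts were removed with edgeR's filterByExpr given the groups, and 16395 genes were tested. Library sizes were scaled with TMM factors, which were 1.05 in the DMSO libraries and 0.934 to 0.973 in the Myrrh libraries. The main test was edgeR's quasi-likelihood F-test (glmQLFit with robust estimation, two-sided, edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The design compared Myrrh with DMSO over all 6 libraries without a block. A second count took the genes that also had a log2 fold change of at least 1. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over the 3 libraries. Where a group had no counts, a fold is a lower bound against a floor of 3 counts per library, and ratios of few counts carry a 95% exact binomial interval; both cover counting error only. As a check for a library deposited more than once, counts were compared within each group; chi-square values were 3.86 to 9.43 per degree of freedom, so no pair agreed within sampling noise. This does not show whether the libraries came from separate cultures.

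Before the data were examined, 47 gene lists with 807 genes were fixed, 30 of these genes in more than 1 list. They covered stress, metabolic, cell cycle, inflammatory, matrix and hormone pathways, signs of RNA quality, and markers of epithelial, stromal, endothelial, leukocyte and smooth muscle cells. Listed genes that did not pass the filter on low counts were not tested, and 1 more was not used here. Lists with at least 5 tested genes, 44 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it, members past the threshold were counted over all genes and adjusted over the list alone. Medians of lists with a gene at 0 in 1 group were the same to 2 decimals with such genes at their bound. The genes named were also fixed by rule: the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap; up to 2 members with the highest and 2 with the lowest values among the called members of a described list; and 14 genes named in advance. Some lists are given by their counts alone. A few genes that this rule selects are not reported here.

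Gene type, position, exons and GC content came from GENCODE release 29 on GRCh38, matched by Ensembl identifier; 16216 of the 16395 tested genes matched. Coordinates are those of the gene, counted from 1, and the number of exons is that of its longest transcript.

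The test was first checked on simulated data. Counts for the 16395 genes were drawn from their mean CPM over all 6 libraries and the fitted dispersions. The same 200 genes were changed by known folds in every set, 50 at each size. A first simulated set had 27 false calls among 178, and 9 more sets were then drawn. Over the 10 sets, 47.4% of genes changed 1.25-fold, 76.8% of those changed 1.5-fold, 74.8% at 2-fold and 97.6% at 4-fold were recovered. False calls made up 8.34% of all calls over the 10 sets (5.7% to 15.2% per set), above the nominal 5%, while 4.89% of unchanged genes had an unadjusted p under 0.05. Nearly all simulated genes were unchanged, whereas 12854 of 16395 were called in the data, so this share does not carry over to those calls. In a simulation of lists, camera called the 1 list of 25 genes raised 1.5-fold and 0 of 40 unchanged lists. Genes were drawn independently of each other there, so this does not check the preset correlation for genes that vary together. Nearly all other genes were unchanged there too. The result therefore does not carry over to lists set against the many called genes of the data.

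The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a filter of 5 CPM in 3 libraries, limma-voom, limma-trend on log2 TPM with pseudocounts of 1 and 0.1, a replicate block, library sizes without mitochondrial genes, glmTreat against a log2 fold change of 0.5, and leaving out each library. For the lists they were an estimated correlation, fry and lists without shared members. Library totals without TMM factors and protein-coding genes alone were added after the data were seen.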

Results

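RNA sequencing libraries were made from 12Z cells, an immortalised line of human endometriotic cells, that is, cells of endometrial type growing outside the uterus. The cells were grown with 10% charcoal-stripped serum and treated for 12 h with an extract of myrrh, the resin of Commiphora trees, at 100 µg/mL in DMSO, or with DMSO alone as the vehicle. Each group had 3 libraries, each made from 1.5 µg of total RNA, and the question was which genes respond to the extract. The DMSO libraries held 22592816, 27588151 and 26356802 estimated gene counts and the Myrrh libraries 24531493, 23923907 and 22454783. Within a group, log2 expression correlated at 0.990 to 0.993 across genes, against 0.920 to 0.926 between groups. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

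In the Myrrh libraries, all 22 HSF1 heat shock chaperones, all 21 ER chaperone and unfolded protein response genes and 28 of 29 ATF4 integrated stress response genes rose. Of the genes of mitosis and G2/M 28 of 29 fell and 1 rose, and all 22 interferon-stimulated genes and all 13 mitochondrially encoded mRNAs fell, as did the type I collagen genes COL1A1 and COL1A2. Camera with a preset correlation called these 6 lists, and with an estimated correlation it called none of them (adjusted p = 0.184 to 0.517 with an estimated correlation). Of 16395 genes tested, 12854 passed an adjusted p of 0.05, with 6436 higher and 6418 lower in Myrrh. A fold change of at least 2 was also reached by 4814 genes, 1859 higher and 2955 lower. A filter of 5 CPM in 3 libraries left 2783 genes of that size, and glmTreat against a log2 fold change of 0.5 called 7483 genes. On the authors' log2(TPM + 1) values, which shrink the folds of low genes, 2921 genes reached that size, 1474 higher and 1447 lower. All these log2 fold changes are Myrrh against DMSO, and gene calls are by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

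The largest changes were taken among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap. The 8 largest increases among these included 5 genes or gene copies of heat shock chaperones. HSPA6, a heat shock protein of the 70-kDa family that is made almost only under stress, went from 0.0596 ± 0.0753 to 1091 ± 126 CPM (read counts scaled to library size; mean ± SD, n = 3). The DMSO libraries held 5 HSPA6 counts in all, and the ratio was 17500, with a 95% counting interval of 7520 to 54000. HSPA7, annotated as an unprocessed pseudogene and near-identical to HSPA6 in sequence, had no counts in DMSO and 18.0 ± 2.93 CPM in Myrrh, at least 160-fold higher against a floor of 3 counts per library. HSPA1A (log2 fold change 6.06 ± 0.07, SE) and HSPA1B (6.02 ± 0.07), near-identical stress-inducible chaperone genes that share reads, reached 18720 ± 624 and 8239 ± 185 CPM from 280 ± 9.09 and 127 ± 2.95. DNAJB1, their co-chaperone, rose by 5.52 ± 0.07, from 77.8 ± 2.52 to 3574 ± 136 CPM. HMOX1, the heme oxygenase induced by oxidative stress, rose by 6.78 ± 0.07, from 52.5 ± 0.758 to 5756 ± 385 CPM. NGFR, the low-affinity neurotrophin receptor, rose by 7.07 ± 0.24 to 12.4 ± 1.06 CPM, and BEX2 by 6.08 ± 0.19 to 13.8 ± 0.782 CPM. NGFR had 7 counts over the DMSO libraries, and its ratio was 142 with a 95% counting interval of 68.7 to 355. The highest adjusted p among these 8 was 4.07e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In GRCh38, HSPA6 lies on chromosome 1 at 161524540 to 161526910 as a gene with 1 exon, HMOX1 on chromosome 22 at 35380361 to 35394214 with 5 exons, and HSPA1A on chromosome 6 at 31815464 to 31817946 with 1 exon.

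The 8 largest decreases, among genes that met the same criteria, included a receptor, a chemokine and 2 noncoding RNAs. SUCNR1, the succinate receptor, went from 10.8 ± 1.25 CPM to 3 counts over the 3 Myrrh libraries, a ratio of 243 with a 95% counting interval of 82.8 to 1180. METTL7A fell by 6.67 ± 0.24 on the log2 scale, and MIR210HG, the noncoding host gene of a hypoxia-responsive microRNA, by 5.80 ± 0.19. METTL7A had 7 counts over the Myrrh libraries, and its ratio was 106 with a 95% counting interval of 51.4 to 265. CCL2, the monocyte-attracting chemokine, fell by 5.39 ± 0.15, from 23.1 ± 2.09 to 0.55 ± 0.109 CPM. PRRT2 (-4.61 ± 0.12), the long intergenic RNA SWINGN (-3.99 ± 0.19) and RCAN2, a regulator of calcineurin (-3.79 ± 0.23), followed. ID1, an inhibitor of DNA-binding helix-loop-helix factors, fell by 3.73 ± 0.08, from 127 ± 6.3 to 9.51 ± 1.36 CPM. The highest adjusted p among these 8 was 9.6e-09, for RCAN2, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In GRCh38, SUCNR1 lies on chromosome 3 at 151873643 to 151884619 with 3 exons, CCL2 on chromosome 17 at 34255218 to 34257203, and ID1 on chromosome 20 at 31605283 to 31606515. The strand setting of the counting is not given in the sources used here, so values of genes that overlap another on the opposite strand are uncertain.

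**Figure D1:**
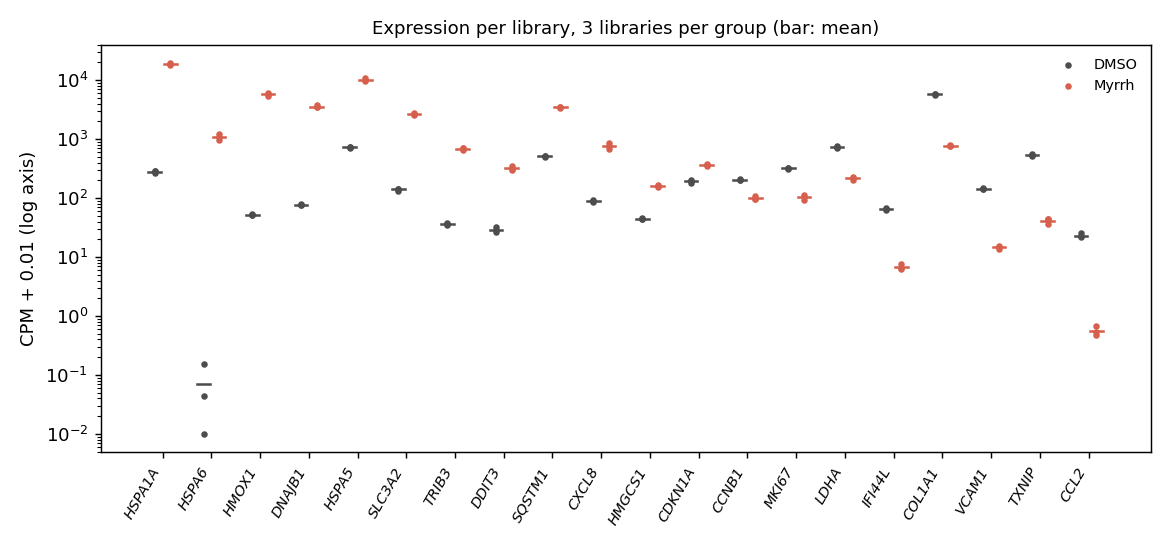
Expression of 20 named genes in each library, in CPM + 0.01 on a log axis, with points for the 3 DMSO and 3 Myrrh libraries and bars for the group means. HSPA1A rose from a mean of 280 to 18720 CPM and COL1A1 fell from 5725 to 762 CPM, and for each gene drawn the libraries of the groups did not overlap. The DMSO library without HSPA6 counts is drawn at 0.01.

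All 22 HSF1 heat shock chaperones rose, with a median log2 fold change of 2.65, and each rose by at least 2-fold. The share of all counts on this list went from 0.721% ± 0.00663 to 6.07% ± 0.148 (SD, n = 3). The camera test with a preset correlation gave the list an adjusted p of 1.62e-10, and adjusted p = 0.268 with an estimated correlation. Adjusted over the list alone, 22 members rose. Of 12 mitochondrial chaperones and proteases, 11 rose and 1 fell (median 0.81), adjusted over the list alone too. HSPD1, the mitochondrial chaperonin, rose by 2.84 ± 0.06 and HSPA9, the mitochondrial 70-kDa chaperone, by 1.83 ± 0.05, and SPG7, a protease of the inner membrane, fell by 1.39 ± 0.06. Camera gave that list an adjusted p of 0.00322, and adjusted p = 0.266 with an estimated correlation. Proteasome subunits rose in 30 of 31 cases, with a median of 0.85, and also in 30 adjusted over the list alone. PSMD11 (1.55 ± 0.05) and PSMD14 (1.53 ± 0.06), both of the regulatory particle, had the highest values. The camera adjusted p of the proteasome list was 5.61e-08, and adjusted p = 0.379 with an estimated correlation.

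The ER chaperone and unfolded protein response list rose in all 21 members, and in 21 adjusted over the list alone, with a median of 1.50. HSPA5, the main chaperone of the ER lumen, went from 727 ± 10.6 to 10200 ± 647 CPM (log2 fold change 3.81 ± 0.06), and its co-chaperone DNAJB9 rose by 3.84 ± 0.07. Camera gave an adjusted p of 3.94e-09, and adjusted p = 0.184 with an estimated correlation. Of 29 ATF4 integrated stress response genes, 28 rose and none fell, and the same numbers held adjusted over the list alone (median 1.41). ATF3, a stress-induced transcription factor, rose by 4.65 ± 0.07 and SLC3A2, a subunit of amino acid transporters, by 4.25 ± 0.06. TRIB3, a pseudokinase, rose by 4.22 ± 0.07 and DDIT3, the transcription factor CHOP, by 3.46 ± 0.07, to 321 ± 27 CPM. The camera adjusted p of the ATF4 list was 1.17e-09, and adjusted p = 0.184 with an estimated correlation.

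NRF2 antioxidant targets rose in 15 of 23 cases and fell in 5, with a median of 0.48, and the counts adjusted over the list alone were 15 and 5. Beside HMOX1, the largest increase was in SRXN1, which reduces oxidised peroxiredoxins (2.38 ± 0.06). The exporter ABCC3 fell by 1.56 ± 0.05 and AKR1C3, a hydroxysteroid dehydrogenase from a family of similar genes, by 0.99 ± 0.17. Camera gave an adjusted p of 0.0196, and adjusted p = 0.402 with an estimated correlation. Without members shared with other lists, HMOX1 among them, the NRF2 list had a camera adjusted p of 0.119. With protein-coding genes alone it was 0.0513, in a range of 0.00755 to 0.119 over the settings with the preset correlation. Iron and heme genes rose in 10 of 14 cases and fell in 3 (median 0.32), with 10 and 3 adjusted over the list alone. TFRC, the transferrin receptor, rose by 1.66 ± 0.10, while the iron exporter SLC40A1 fell by 0.50 ± 0.09 and GPX4, which reduces lipid peroxides, by 0.31 ± 0.06. Its camera adjusted p was 0.0412, and adjusted p = 0.268 with an estimated correlation. That call held in 7 of 14 settings with the preset correlation, in a range of adjusted p from 0.0363 to 0.313. Among others, it was lost without DMSO replicate 2 (0.0503), without Myrrh replicate 3 (0.055), with a filter of 5 CPM in 3 libraries (0.12) and without shared members (0.313). Of 6 metallothionein and zinc export genes, 5 rose and none fell, also adjusted over the list alone, with a median of 1.93. SLC30A1, the zinc exporter, rose by 2.10 ± 0.05, and MT1G, at 0 counts in DMSO, was at least 4.48-fold higher at 0.505 ± 0.0396 CPM. The metallothionein genes are similar in sequence and can share reads. Camera gave an adjusted p of 0.019, and adjusted p = 0.379 with an estimated correlation.

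Autophagy and lysosome genes rose in 21 of 25 cases and fell in 1, with the same numbers adjusted over the list alone and a median of 0.99. RRAGD, a GTPase that signals nutrients at the lysosome, rose by 4.85 ± 0.23 and SQSTM1, the autophagy receptor p62, by 2.76 ± 0.06, to 3449 ± 103 CPM. The kinase gene ULK1 fell by 0.47 ± 0.06. Camera gave an adjusted p of 3.5e-06, and adjusted p = 0.184 with an estimated correlation. Cholesterol synthesis genes rose in 21 of 25 cases and fell in 2, also adjusted over the list alone, with a median of 1.20. INSIG1, which holds the sterol sensor in the ER, rose by 2.57 ± 0.06, the sterol oxidase MSMO1 by 2.52 ± 0.07 and HMGCS1, which makes HMG-CoA, by 1.86 ± 0.05. TM7SF2, a sterol reductase, fell by 0.89 ± 0.10 and LSS, lanosterol synthase, by 0.19 ± 0.06, a call that was lost on log2(TPM + 1) of every gene above 0. The camera adjusted p was 6.52e-06, and adjusted p = 0.268 with an estimated correlation. Fatty acid synthesis genes rose in 8 of 11 cases and fell in 2, also adjusted over the list alone, but camera did not call the list (adjusted p = 0.121). SCD, the stearoyl-CoA desaturase, rose by 1.26 ± 0.06 and ACSL3 by 0.97 ± 0.06, and SREBF1 fell by 0.34 ± 0.05. The elongase gene ELOVL6 was lower in estimated counts (-0.49 ± 0.07) and higher on the authors' log2(TPM + 1) values (0.37). Ribosome biogenesis genes rose in 17 of 18 cases, also adjusted over the list alone, with a median of 0.75, led by RRP9 (1.53 ± 0.07) and POLR1B (1.22 ± 0.07). Camera gave that list an adjusted p of 4.45e-05, and adjusted p = 0.268 with an estimated correlation.

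**Figure D2:**
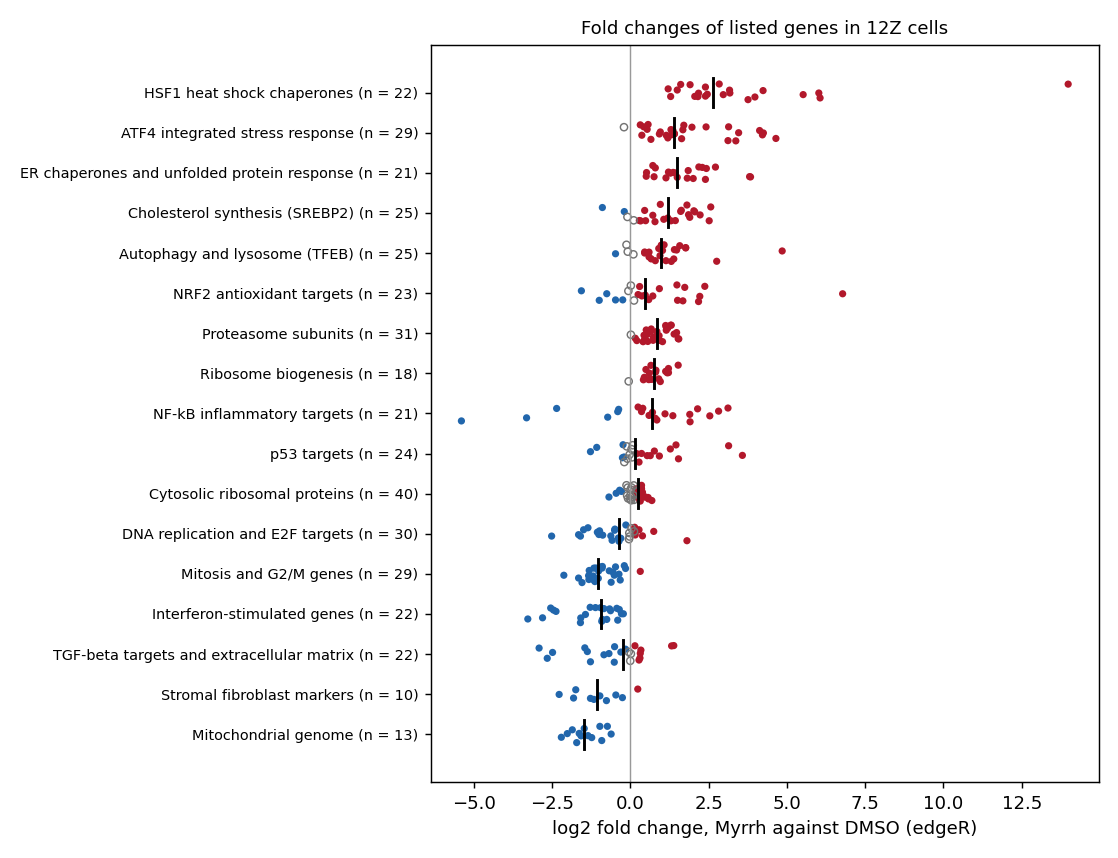
Log2 fold changes of the tested members of 17 gene lists, Myrrh against DMSO, with 1 point per gene, filled red (higher) or blue (lower) where the gene passed an adjusted p of 0.05 and open where it did not, and a black line at each median. The heat shock list has a median of 2.65 and the mitochondrial genome list a median of -1.47, while the lists of NF-kB and p53 targets hold members on both sides of 0.

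Genes of mitosis and G2/M fell in 28 of 29 cases, with 1 rise, and adjusted over the list alone the numbers were 28 and 1. The median was -1.02. KIF20A, a kinesin of cytokinesis, fell by 2.12 ± 0.06 and MKI67, the proliferation marker Ki-67, by 1.65 ± 0.06, from 322 ± 8.74 to 103 ± 8.27 CPM. CCNB1, the mitotic cyclin, fell by 1.04 ± 0.05, and CDC20, an activator of the anaphase-promoting complex, rose by 0.32 ± 0.06, a call that was lost on the authors' log2(TPM + 1) values (0.16). Camera gave an adjusted p of 7.75e-08, and adjusted p = 0.268 with an estimated correlation. DNA replication and E2F targets fell in 18 of 30 cases and rose in 7, or 18 and 8 adjusted over the list alone, with a median of -0.35. E2F8 fell by 2.51 ± 0.12 and CCNE2, a cyclin of S phase entry, by 1.65 ± 0.08, while the replication licensing factor CDC6 rose by 1.81 ± 0.05 and MCM10 by 0.75 ± 0.07. Its camera adjusted p was 0.0412, and adjusted p = 0.519 with an estimated correlation. The call was lost without DMSO replicate 3 (0.0531), Myrrh replicate 1 (0.063) or Myrrh replicate 2 (0.0711). Histone transcripts fell in 6 of 7 cases (camera adjusted p = 0.0612), and adjusted over the list alone 1 rose and 6 fell. H2BC21 was at -2.33 ± 0.16 and H2BC4 at -1.88 ± 0.42, the latter from 0.725 to 0.19 CPM. Camera called the histone list without Myrrh replicate 3 (adjusted p 0.0426) and on log2(TPM + 1) (0.0308), in a range of 0.0308 to 0.0798 over the settings with the preset correlation.

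Among p53 targets 12 of 24 rose and 5 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.148). GADD45A rose by 3.58 ± 0.07, SESN2, also in the ATF4 list, by 3.14 ± 0.06 and CDKN1A, the cell cycle inhibitor p21, by 0.93 ± 0.06. The repair genes POLH (-1.27 ± 0.07) and DDB2 (-1.07 ± 0.06) fell. The other 7 were not called, with MDM2 (-0.09), BAX (0.06) and BBC3 (0.04) among them. Pro-apoptotic genes rose in 12 of 20 cases and fell in 2, also adjusted over the list alone, with a median of 0.45. HRK, at 0 counts in DMSO and 1.46 ± 0.474 CPM in Myrrh, was at least 13-fold higher (a floor of 3 counts per library), and the death receptor TNFRSF10A rose by 1.82 ± 0.08. BMF fell by 1.18 ± 0.12 and APAF1, the core of the apoptosome, by 0.70 ± 0.08. Camera gave this list an adjusted p of 0.0299, and adjusted p = 0.268 with an estimated correlation. The call held in 11 of 14 settings with the preset correlation, in a range of adjusted p from 0.0186 to 0.231. It was lost with library totals (0.0505) and with protein-coding genes alone (0.111). It was also lost with a filter of 5 CPM in 3 libraries, where the median was 0.08 and the adjusted p 0.231. Of 9 anti-apoptotic genes, 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.409), with BCL2 at 1.01 ± 0.15, XIAP at 0.71 ± 0.06, CFLAR at -1.08 ± 0.06 and BIRC5 at -0.36 ± 0.05.

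All 22 interferon-stimulated genes tested fell, also adjusted over the list alone, with a median of -0.93. IFI44L fell by 3.27 ± 0.08, from 65.1 ± 2.64 to 6.76 ± 0.766 CPM, and the antiviral GTPase MX2 by 2.79 ± 0.13. The camera adjusted p was 1.86e-06, and adjusted p = 0.268 with an estimated correlation. NF-kB targets moved both ways, with 15 of 21 higher and 6 lower, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.0932), except with library totals in place of TMM factors (0.0467; range 0.0467 to 0.139 over the settings with the preset correlation). The neutrophil chemokine CXCL8 rose by 3.12 ± 0.08, from 88.5 ± 3.54 to 771 ± 89.1 CPM, CXCL3 by 2.82 ± 0.10 and IL6 by 1.36 ± 0.12. Besides CCL2, the adhesion molecule VCAM1 fell by 3.31 ± 0.06, from 144 ± 3.36 to 14.5 ± 0.953 CPM. In the prostaglandin pathway 6 of 10 genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.329). The prostaglandin receptor PTGER4 rose by 1.51 ± 0.30, to 1.54 ± 0.0471 CPM, a call that was lost on log2(TPM + 1) of every gene above 0. PTGS2, the inducible cyclooxygenase, rose by 1.11 ± 0.12, while PTGIS fell by 1.46 ± 0.14 and PTGES, a prostaglandin E synthase, by 0.64 ± 0.07.

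Immediate early and MAPK feedback genes rose in 18 of 27 cases and fell in 6, also adjusted over the list alone, with a median of 0.69. Beside ATF3, the phosphatase gene DUSP8 rose by 4.41 ± 0.14, and the AP-1 subunits FOS (-2.42 ± 0.21) and JUNB (-1.66 ± 0.10) fell. Camera gave an adjusted p of 0.0145, and adjusted p = 0.517 with an estimated correlation. With a filter of 5 CPM in 3 libraries the adjusted p was 0.0584, in a range of 0.0056 to 0.0584 over the settings with the preset correlation. Growth factor genes rose in 7 of 12 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.247). HBEGF, a ligand of the EGF receptor, rose by 3.07 ± 0.08, PGF by 2.03 ± 0.07 and VEGFA, the vascular growth factor, by 0.72 ± 0.05, while PDGFB fell by 1.82 ± 0.12 and ANGPT1 by 1.65 ± 0.27, the last a call that was lost on log2(TPM + 1) of every gene above 0.

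TGF-beta and extracellular matrix genes fell in 12 of 22 cases and rose in 7, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.116). The chains of type I collagen fell, COL1A1 by 2.91 ± 0.06, from 5725 ± 164 to 762 ± 17.1 CPM, and COL1A2 by 2.65 ± 0.06. THBS1, a thrombospondin, rose by 1.32 ± 0.06. Stromal fibroblast markers moved with the collagens, with 9 of 10 lower and 1 higher, also adjusted over the list alone, and a median of -1.07. LUM, a proteoglycan, fell by 2.27 ± 0.06 and the growth factor receptor PDGFRA by 1.81 ± 0.11, and MME was higher by 0.24 ± 0.06, a call that was lost with upper-quartile factors, with library totals and on log2(TPM + 1) of every gene above 0. Camera gave the stromal list an adjusted p of 0.0047, and adjusted p = 0.268 with an estimated correlation. Epithelial markers went both ways, with 6 of 11 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.852). CLDN1 rose by 2.96 ± 0.09 and EPCAM by 1.13 ± 0.23, the latter from 1.04 to 2.28 CPM. MUC1 fell by 2.46 ± 0.09 and CLDN4 by 1.28 ± 0.17. Smooth muscle markers fell in 5 of 8 cases, also adjusted over the list alone (camera adjusted p = 0.148). DES was at -1.99 ± 0.39, from 0.84 to 0.21 CPM, and LMOD1 at -1.88 ± 0.16. Too few endothelial (2) and leukocyte (3) markers passed the filter for a set test. ESAM and EGFL7 fell, PTPRC and CD14 fell, and CD68, which lysosomes of many cells carry, rose by 0.84 ± 0.07, and the same genes were called adjusted over each list alone. PTPRC rested on 46 counts over the DMSO and 5 over the Myrrh libraries; its call was lost on the log2 TPM values with either pseudocount, and that of ESAM on log2(TPM + 1) of every gene above 0.

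Of 10 matrix protease genes and inhibitors, 4 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.513, median -0.40, mean 0.26). MMP1, the interstitial collagenase, rose by 4.08 ± 0.13 and MMP3 by 2.37 ± 0.46, the latter from 0.151 to 0.793 CPM. MMP11 fell by 1.63 ± 0.13, PLAU, the urokinase, by 1.13 ± 0.06 and MMP2, a gelatinase, by 0.58 ± 0.06. Mesenchymal transition factors rose in 6 of 10 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.551, median 0.32, mean -0.06), with TWIST2 and ZEB2 both at 1.07 ± 0.06, S100A4 at -2.02 ± 0.15 and CDH11 at -1.97 ± 0.54. CDH11 rested on 43 counts over the DMSO and 9 over the Myrrh libraries, and its call was lost on log2(TPM + 1) (-0.33). Steroid hormone and decidual genes rose in 5 of 13 cases and fell in 7, also adjusted over the list alone (camera adjusted p = 0.388). GREB1, an estrogen-responsive gene, rose by 1.39 ± 0.28, from 0.867 to 2.27 CPM. The estrogen receptor gene GPER1 rose by 1.24 ± 0.17, from 1.8 to 4.26 CPM. STAR, which brings cholesterol into mitochondria, fell by 2.48 ± 0.21. HOXA10, a homeobox gene of the uterus, fell from 45.0 ± 2.22 to 11.7 ± 0.767 CPM (-1.95 ± 0.07).

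The 13 mRNAs of the mitochondrial genome all fell, also adjusted over the list alone, with a median of -1.47. Their share of all counts went from 13.5% ± 0.34 to 4.69% ± 0.477 (SD, n = 3), and the share of the mitochondrial rRNA genes from 0.889% ± 0.0162 to 2.88% ± 0.353. A two-sided exact permutation test gave p = 0.1 for each share, the smallest value that 3 against 3 libraries allow. MT-ND6, a complex I subunit and the mRNA encoded on the opposite strand, fell by 2.20 ± 0.07. The strand setting of the counting is not given, so the MT-ND6 value may include reads of the other strand. MT-CO1, a subunit of cytochrome oxidase, fell by 2.01 ± 0.07, from 30790 ± 822 to 7626 ± 895 CPM. MT-RNR1 rose by 3.13 ± 0.09 and MT-RNR2 by 1.65 ± 0.09. Camera gave the mRNA list an adjusted p of 4.63e-05, and adjusted p = 0.517 with an estimated correlation. Nuclear-encoded subunits of oxidative phosphorylation rose in 8 of 35 cases and fell in 15, also adjusted over the list alone (camera adjusted p = 0.247), from ATP5MC1 at -1.09 ± 0.06 and NDUFB3, which fell from 45.0 ± 2.28 to 22.5 ± 1.66 CPM, to SDHB at 0.43 ± 0.05 and UQCRFS1 at 0.58 ± 0.06.

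**Figure D3:**
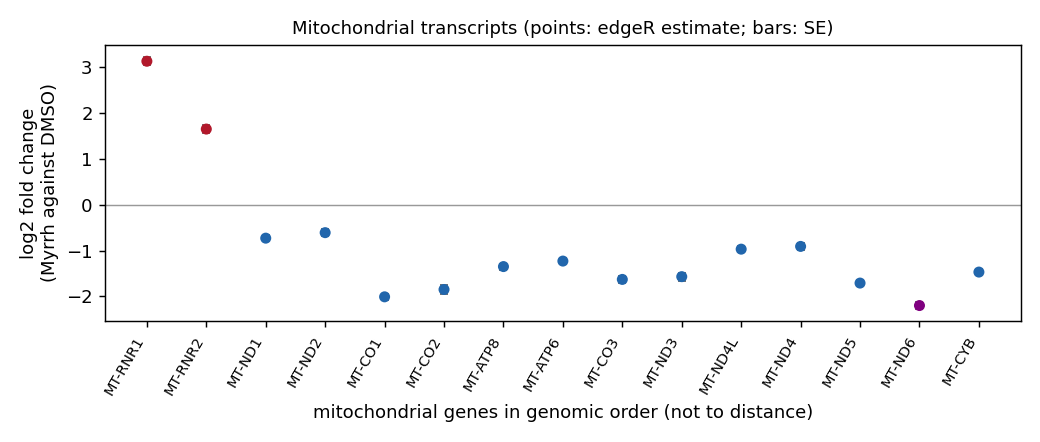
Log2 fold changes of the mitochondrially encoded genes, Myrrh against DMSO, in genomic order, with rRNAs in red, mRNAs in blue and the mRNA of the other strand in purple; error bars are SE and mostly smaller than the points. The rRNAs lie at 3.13 and 1.65 and the mRNAs between -2.20 and -0.61.

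Hypoxia and glycolysis genes rose in 9 of 25 cases and fell in 10, also adjusted over the list alone (camera adjusted p = 0.618). Hexokinase HK2 rose by 1.20 ± 0.05 and the glucose transporter SLC2A3 by 1.11 ± 0.05, while ALDOC fell by 2.23 ± 0.26 and LDHA, lactate dehydrogenase A, 3.37-fold, from 734 ± 31.3 to 218 ± 15 CPM. FOXO targets rose in 5 of 9 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.743, median 0.18, mean -0.23). IRS2 rose by 1.51 ± 0.06 and FBXO32 by 0.92 ± 0.07, CITED2 fell by 1.03 ± 0.06, and TXNIP, an inhibitor of thioredoxin and glucose uptake, fell by 3.68 ± 0.07, from 533 ± 16.7 to 41.5 ± 4.08 CPM. Glucocorticoid receptor targets rose in 3 of 8 cases and fell in 4, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.847, median -0.23, mean 0.29), with DUSP1 at 2.84 ± 0.11, TSC22D3 at 1.28 ± 0.07, CEBPD at -1.76 ± 0.06 and NFKBIA at -0.37 ± 0.05.

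Camera did not call the remaining lists, and the counts that follow are the same over all genes and adjusted over the list alone. LXR targets rose in 2 of 8 cases and fell in 6 (adjusted p = 0.162), AhR targets in 3 and 1 of 6 (0.53), mitophagy genes in 6 and 4 of 12 (0.472), and YAP targets in 11 and 5 of 20 (0.268). Wnt targets rose in 4 and fell in 2 of 7 cases (0.53), Notch targets in 5 and 1 of 6 (0.223), cytosolic ribosomal proteins in 23 and 4 of 40 (0.0633), and tubulins in 2 and 7 of 11 (0.247). Camera called the ribosomal protein list without Myrrh replicate 1 (adjusted p 0.00851) and on log2(TPM + 1) (0.0275), in a range of 0.00851 to 0.411 over the settings with the preset correlation. Of the 2 LXR targets that rose, PLTP (0.20 ± 0.09; adjusted p 0.0496 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) had overlapping groups and lost its call under 14 alternatives. Of 12 housekeeping controls, 4 rose and 6 fell (0.764, median -0.11, mean 0.11), with PPIA at -1.16 ± 0.06, ACTB at -0.69 ± 0.06 and RPLP0 at 0.57 ± 0.06. Of PXR and FXR targets 2 were tested, without a set test, and CYP3A5 fell by 0.63 ± 0.13.

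Of 44 lists tested, camera with the preset correlation called 18, of which 13 were higher and 5 lower, and fry, which tests whether the genes of a list move on balance one way, called 41. With an estimated correlation camera called 0 of them at an adjusted p of 0.05, and 7 at an unadjusted p of 0.05, with 0.184 as the lowest adjusted p.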

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

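Library totals without TMM factors and protein-coding genes alone were chosen after seeing the data; all other alternatives were fixed before. The count of 12854 genes stayed within 1.5 times under every alternative except glmTreat, which asks for a log2 fold change beyond 0.5 and called 7483. Leaving out 1 library gave 12276 to 12688 genes, 4767 to 4894 genes of at least 2-fold, and 17 to 18 lists. The count of 4814 genes of at least 2-fold was 2783 with a filter of 5 CPM in 3 libraries, which tests fewer genes (11912). It was 2921 on log2(TPM + 1) and 2999 on log2(TPM + 1) of every gene above 0, where the pseudocount shrinks the folds of low genes. The share of higher genes was 50.5% and 49.8% there, against 38.6% in the main count. That share was 30.4% with upper-quartile factors and 29.3% with library totals. Upper-quartile factors and library totals moved the median of all genes from -0.02 to -0.14 and -0.16, and the share of higher genes among all calls from 50.1% to 42.8% and 41.8%. Small changes are relative to that shift: under library totals the median of the p53 list was 0. The 18 lists called became 0 with an estimated correlation and 41 with fry. Fry asks whether a list moves on balance, not whether it moves more than other genes do, and 12854 of 16395 genes were called. It also called the housekeeping list, so a call by fry sets a list apart little. Why the estimated correlation left 0 was not tested. With the preset correlation, 13 of the 18 were called under every setting run; the metallothioneins had too few genes under the 5 CPM filter for a test. The other 5 were DNA replication, iron and heme, immediate early, NRF2 and pro-apoptotic genes. Ribosomal protein, histone and NF-kB lists, not called in the main test, were called under 2, 2 and 1 of these settings. Reversals were few. ELOVL6, lower in counts (-0.49), was higher on log2(TPM + 1) (0.37), on log2(TPM + 0.1) (0.42) and on log2(TPM + 1) of every gene above 0 (0.37). Fry gave an upward direction to the glucocorticoid receptor list (median -0.23) and the housekeeping list (-0.11), whose means are above 0. The epithelial list had a median of -0.40 with the 5 CPM filter and, on log2(TPM + 1), a downward direction with a median of 0.15. The cause of these reversals was not tested. Among values for named genes, 43 of the alternative values lost the call and 3 reversed, against 3215 that did neither.

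The replicate numbers did not pair the libraries: deviations from the group means correlated at -0.06, -0.00454 and 0.04 for numbers 1, 2 and 3, and 1 of 6 libraries correlated best with its own number. With a replicate block, 12782 genes passed, 4823 of them at least 2-fold, and 17 lists, without the DNA replication list (adjusted p 0.0617).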

Other observations

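The gene families of this paragraph were chosen after their values were seen. HOX genes, the homeobox genes of body patterning, fell in 26 of 33 cases and rose in 2, with a median log2 fold change of -0.95. HOXB5 fell by 3.37 ± 0.11 (SE) and HOXB3 by 3.07 ± 0.06, from 139 ± 4.12 CPM (SD, n = 3) in DMSO, while HOXB9 rose by 1.31 ± 0.08. Collagen chains fell in 21 of 24 cases and rose in 2 (median -1.16), so the fall was not limited to type I; COL16A1 fell by 2.71 ± 0.09 and COL6A2 rose by 0.35 ± 0.06. Cytosolic aminoacyl-tRNA synthetases rose in 18 of 19 cases (median 0.94), with GARS1 at 1.68 ± 0.06 and YARS1 at 1.53 ± 0.06 as the highest, and QARS1 fell by 0.65 ± 0.05. Their mitochondrial counterparts rose in 12 of 17 cases and fell in 4 (median 0.32), with EARS2 at 1.55 ± 0.06 and VARS2 at -1.56 ± 0.09. Mitochondrial ribosomal proteins rose in 50 of 78 cases and fell in 11 (median 0.31), beside the fall of the mRNAs they translate. DNAJ co-chaperones rose in 28 of 39 cases and fell in 7 (0.50), dual-specificity phosphatases in 12 of 19 and 4 (0.80), and ZNF genes in 227 of 420 and 98 (0.33). Calls in this paragraph are by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

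Of the tests that follow, those of mitochondrial content, of the order along the mitochondrial genome and of lncRNA levels were chosen only after the result was seen, and the poly(A) test was changed after its first result. The 13 mitochondrial mRNAs fell while both mitochondrial rRNAs rose. A lower content of all mitochondrial RNA would by itself lower both rRNAs if capture was alike in both groups. The smaller of their log2 fold changes was 1.65. Equal capture is not shown by the test that follows, so lower content combined with less strict poly(A) selection in the Myrrh libraries stays open. The scalings run gave mRNA medians of -1.62 to -1.47, too narrow a range to test scaling. A scaling factor moves mRNAs and rRNAs of a library alike, so none of them could alter the gap between these genes. Less strict poly(A) selection in the Myrrh libraries would raise RNAs without a poly(A) tail; their median was -0.80 over 13 RNAs with identical copies counted once (-0.67 over 21 in the first form), below the bound of 0 set in advance, yet that bound was wrong because 7 of them are histone transcripts, which fall when fewer cells replicate DNA. The 7 histone transcripts differed by -0.99 ± 0.04 (SE over libraries) and the other 6 RNAs by -0.02 ± 1.27, so this explanation cannot be told apart from a response of the cells. One hypothesis, that mRNAs farther from the heavy-strand promoter fell more, was not borne out across 12 mRNAs (Spearman's rho -0.17, two-sided permutation test over genes, p = 0.6), and a change in the processing or turnover of mitochondrial RNA under Myrrh stays open as an untested hypothesis.

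Long noncoding RNAs fell as a class: of 2125 tested, 1228 fell and 284 rose, with a median of -0.80, against 0.09 for 13168 coding genes and 0.05 for 320 processed pseudogenes. Other pseudogene classes were lower as well, with medians of -0.48 (unprocessed, 31 of 73 fell and 19 rose), -0.41 (transcribed processed, 35 of 83 and 15) and -0.26 (transcribed unprocessed, 98 of 229 and 52), so the fall was not particular to lncRNAs. Low counts do not account for all of it. At 8 CPM or more the lncRNA median was still lower by 0.68 (a difference of -0.68 between 269 lncRNA and 10310 coding genes), against a difference of -0.89 at all levels. This does not cover the lncRNAs below 8 CPM, which are most of the 2125. GC content is argued against by a difference of -0.91 after the trend in coding genes was removed (-0.89 before), while other scalings decide nothing here, since a scaling factor moves all genes of a library alike and the smallest difference stayed at -0.89. Less carry-over of unspliced or nuclear RNA, and reads of coding genes counted for overlapping antisense genes, were not tested and stay open, beside an effect of Myrrh on these transcripts.

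HSPA7, with no counts in DMSO, had 387, 478 and 351 estimated counts in the Myrrh libraries, 1.65% of those of HSPA6. Reads shared with HSPA6 are a candidate source: the HSPA7 value was not whole in 2 of the 3 Myrrh libraries. This shows that some reads were split, not how many, so HSPA7 transcription and shared reads cannot be told apart.

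With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 12854 genes and the highest of the others 0, with 1 of 10 splits as large. For genes of at least 2-fold these were 4814 and 0, again 1 of 10. For lists they were 18 and 18, with 2 of 10 splits as large. The 9 mixed splits gave 0 genes each, and 11 to 18 lists with the preset correlation. Each mixed split holds both treatments in unequal numbers on either side. Part of the treatment difference therefore stays in the comparison, and the rest enters the spread within groups. So neither their genes nor their lists measure what arises without a treatment difference, and no conclusion is drawn from them. Genes with at least 1 count numbered 24030 ± 271 in DMSO and 22560 ± 365 in Myrrh (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible).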
